A study of Populus trichocarpa
Laccaria bicolor and Populus trichocarpa with 60 samples.

How the data were processed

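Per the labels, total RNA of leaves and roots was made into stranded cDNA libraries and sequenced on an Illumina HiSeq instrument. The plants were rooted cuttings of the western poplar Populus trichocarpa, clone 101-74, grown in clay with or without inoculum of Laccaria bicolor, an ectomycorrhizal fungus that forms a sheath around fine roots. Inoculated plants are written I and non-inoculated plants NI. Each treatment lasted for the time before harvest that the labels give: 8 h of ozone at 200 nmol per mol of air, or 43 h without watering, against watered plants in coal-filtered air. Leaves 9 and 10 from the apex, bare fine roots and, from inoculated plants, fine roots enriched in mycorrhizal tips were sampled. A replicate was a pool of 3 to 4 plants, and each of the 15 groups had 4 replicates, 60 libraries in all. Replicates were therefore separate pools of plants, and libraries of different organs with the same number within one treatment and inoculation came from the same pool, per the labels.

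The authors deposited 1 table per library with read counts per gene, which are whole numbers, and a second column of the same counts divided by a size factor, per the file headers. The submitters' processing notes name TopHat2 2.12, Bowtie and DESeq2 without further settings. The genome build and gene annotation are not given in the sources used here. Every table held the same 34699 poplar gene rows, with no row that names no gene. The second column gave no value for 6538 genes and a value for the other 28161. The size factors computed here from the counts over all 60 libraries differed from the deposited ones by at most 7.4e-12. The second column was used for that comparison alone, and all tests were run on the deposited counts. The gene rows carry Potri identifiers and the files do not pair them with names. Of these, 0 were found in the table of 34621 named genes that was at hand, so no gene name, function or position is given, and 0 of the 39 gene lists prepared beforehand could be matched or tested. At most 2 identifiers per direction and comparison are printed for the same reason. Checks of GC content and gene length were void because no gene had a value. Fungal genes were not analysed here.

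The total count per library ran from 12545102 to 26596723, with at least 18537655 in leaves, 13918169 to 23084599 in bare roots and at most 17809360 in mycorrhiza-enriched roots. No pair of libraries of a group agreed within sampling noise, the lowest mean chi-square per gene being 4.85. The choices in this paragraph and the next were made before the data were examined, apart from those named as added. Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, the filterByExpr filter by group, a quasi-likelihood fit with robust estimation and 1 coefficient per group. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene is called changed at an adjusted p under 0.05. Leaves and bare roots were fitted separately with their 6 groups each, mycorrhiza-enriched roots with their 3 groups. Mycorrhiza-enriched roots were set against bare roots of inoculated plants in a fit of these 24 libraries, and against roots of non-inoculated plants in a fit of the 12 control libraries below ground. An interaction is the difference between 2 treatment effects. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are CPM, counts relative to TMM-scaled library sizes, given as mean ± SD. In all, 20 comparisons were made.

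The identifiers named were those with the largest rise or fall among genes with an adjusted p under 0.05, a log2 fold change of at least 1 in size, a mean of at least 5 CPM and no overlap between the compared libraries (no such separation for interactions). Some were left out for length. Where a comparison called 1 gene outside this rule, that gene is named and was chosen after its values were seen. Alternatives were DESeq2 1.42.0 with its own size factors, RLE factors in edgeR, no filter on low counts, the replicate number or the pool as a block, a fit of the compared groups alone, a minimum log2 fold change of 1, and leaving out each library in turn. The pool pairs bare and mycorrhiza-enriched roots of inoculated plants by the labels. The mean correlation of same-numbered deviations from the group means was 0.165 in controls, -0.01 under ozone and 0.093 under stopped watering. Across treatments and inoculation the replicates share only a number.

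Because identifiers could not be named, groups of genes were defined by a comparison and followed in libraries outside the compared groups. This was added after the files had been examined. Some of these libraries were in the fit that gave the calls and shared its filter, scaling and estimate of the spread. They were non-inoculated leaves for ozone genes and bare roots of inoculated plants for stopped-watering genes. For genes that differed between mycorrhiza-enriched and bare roots, they were the ozone and unwatered roots of inoculated plants. Their scores are therefore not fully independent of the choice of genes. The score of a library is the median over the group's genes of the log2 CPM (prior count of 2) minus the mean of the reference libraries. Scores of 4 against 4 libraries were compared by an exact two-sided permutation test, whose smallest p is 0.0286. It is called exact because every arrangement of the scores was used. The reference mean was not recomputed for each arrangement, so that its p-values are approximate. Over the 34 such tests the smallest adjusted p was 0.0971, so that no score passed the correction. The overlap of inoculated and non-inoculated responses was set beside the number that independent lists of the same length would share.

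The tests were tried on simulated data in which 200 genes of the real means, dispersions and library sizes were changed. In the simulation of inoculated leaves under ozone, over 25249 genes, 71% of the genes changed 2-fold and 92% of those changed 4-fold were recovered, with 12 false calls. For non-inoculated roots without watering, over 27553 genes, these shares were 71% and 95%. For mycorrhiza-enriched against bare roots of inoculated plants, over 27085 genes, they were 73% and 91%. For the leaf interaction of ozone with inoculation, over 25249 genes, they were 46% and 82%. The simulations drew genes independently and gave each gene the same dispersion in all groups. Real genes vary together, and the real ozone leaves varied more between replicates than their controls. The shares may therefore be too high for the real comparisons, those with ozone above all.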

Results

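Messenger RNA was counted in poplars that had or had not been inoculated with the ectomycorrhizal fungus Laccaria bicolor and were then exposed to ozone, left without water or kept as controls. There were 6 groups of leaves, 6 of bare fine roots and 3 of mycorrhiza-enriched fine roots, with 4 pools of plants in each. Mean totals per group lay between 15693955 counts in mycorrhiza-enriched roots without watering and 26067334 in inoculated leaves under ozone. The series asks how each organ responds to the 2 stresses and whether the symbiosis alters that response. Genes are given by identifier, since the files and the gene table used here do not pair identifiers with names.

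**Figure D1:**
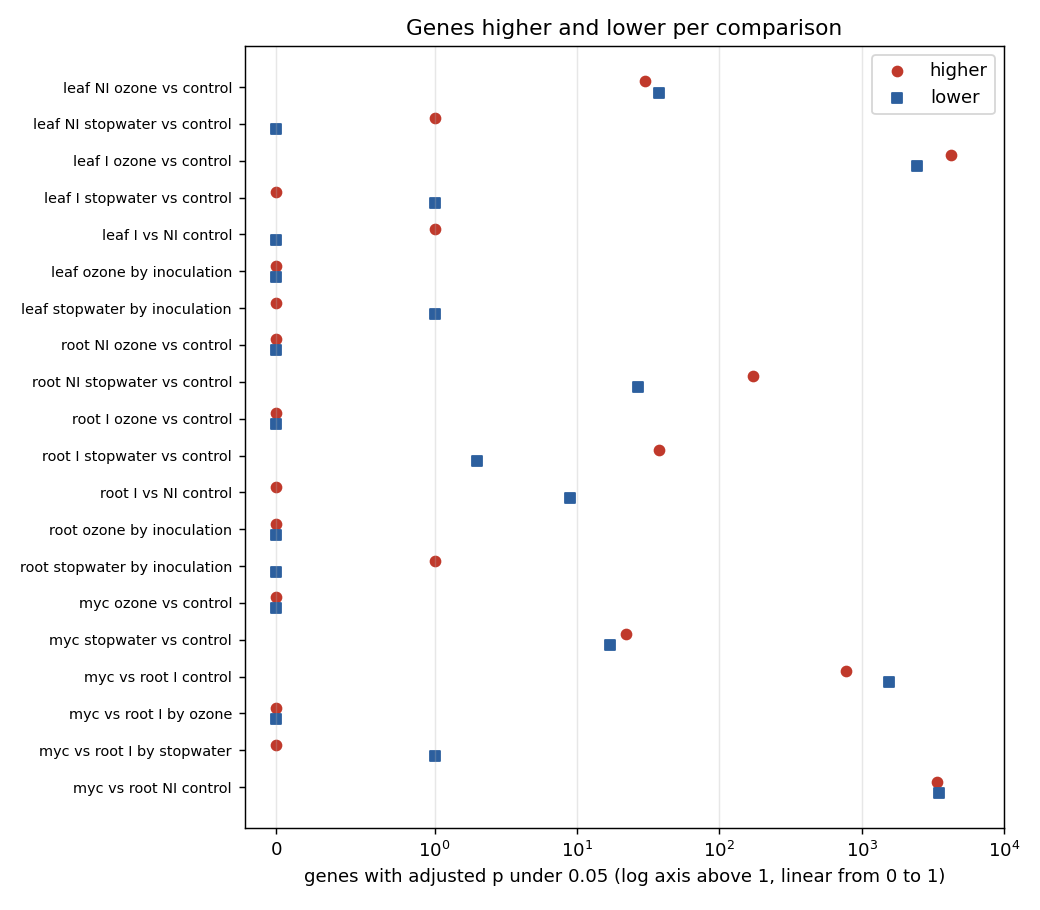
Number of genes with an adjusted p under 0.05 in each of the 20 comparisons, on an axis that is logarithmic above 1, with circles for genes higher and squares for genes lower in the first-named group or, for interactions, with a larger or smaller effect. Ozone in inoculated leaves (4227 higher, 2446 lower) and mycorrhiza-enriched against non-inoculated roots (3368 higher, 3518 lower) gave the most calls.

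The first question was how ozone altered leaves. In leaves of inoculated plants, 4227 genes were higher and 2446 lower than in their controls, out of 25249 tested. The genes that rose also moved further: 2258 of them but 63 of the falling genes changed by at least 1 on the log2 scale. Potri.014G113500 rose from 0.743 ± 0.302 CPM in controls to 224 ± 249 CPM under ozone (SD, n = 4 each), a log2 fold change of 8.22 (SE 1.26, edgeR adjusted p = 0.000834), with ozone libraries ranging from 24.7 to 561.0 CPM. Potri.004G018600 fell from 14.4 ± 0.617 to 5.41 ± 1.54 CPM (SD, n = 4 each; log2 fold change -1.41, SE 0.17, edgeR adjusted p = 0.000439), and Potri.019G073800 from 12.7 ± 0.975 to 4.68 ± 2.87 CPM (SD, n = 4 each; log2 fold change -1.44, SE 0.38, edgeR adjusted p = 0.00864). The count fell to 2821 when only the compared groups were fitted. It was 3279 without ozone replicate 3 and 4399 without ozone replicate 4.

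In leaves of non-inoculated plants, ozone raised 30 genes and lowered 38. Potri.001G218800 rose from 5.05 ± 1.87 to 38.4 ± 30.0 CPM (SD, n = 4 each; log2 fold change 2.92, SE 0.56, edgeR adjusted p = 0.0306) and Potri.014G150200 from 23.5 ± 2.96 to 110 ± 62.5 CPM (SD, n = 4 each; log2 fold change 2.22, SE 0.41, edgeR adjusted p = 0.028). Potri.010G132000 fell from 102 ± 28.2 to 47.4 ± 8.93 CPM (SD, n = 4 each; log2 fold change -1.11, SE 0.20, edgeR adjusted p = 0.0202) and Potri.012G115400 from 17.5 ± 6.27 to 7.98 ± 0.84 CPM (SD, n = 4 each; log2 fold change -1.13, SE 0.23, edgeR adjusted p = 0.0374). The count of 68 depended on single libraries. It was 668 without ozone replicate 1, 569 without ozone replicate 3 and 2 without ozone replicate 2 or 4; it was 11, 39 and 1 without control replicates 2, 3 and 4. DESeq2 called 1150 genes, and a fit of the compared groups alone called 1.

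The genes that ozone raised in inoculated leaves were mostly higher in the non-inoculated leaves too: 93.1% of them had a positive log2 fold change there, with a median of 0.45 against 1.09 in inoculated leaves. Of the falling genes, 84.9% were negative in non-inoculated leaves, with medians of -0.15 and -0.43. Both comparisons called 25 genes higher, where independent lists would share 5.02, and 16 lower, where they would share 3.68. Across the 25249 genes, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.78. As a score, the 4227 rising genes stood at 0.40 ± 0.44 in the non-inoculated ozone libraries and 0.00 ± 0.10 in their controls (SD, n = 4 each), with an exact permutation p of 0.171 (adjusted p = 0.307). The ozone libraries scored 0.81 and 0.75 in replicates 2 and 4 but 0.03 and 0.01 in replicates 1 and 3. Whether inoculation changed the ozone effect was tested as an interaction: edgeR called 0 genes, and DESeq2 called 5. In edgeR 3250 genes had an unadjusted p under 0.05, where 1262 are expected by chance on average. Since genes vary together, the number can lie far from such an average by chance, here and in the paragraphs below. In draws with exchanged inoculation labels, up to 1425 genes passed even the adjusted threshold, so that 3250 is not shown to exceed chance. For the mean ozone effect over both inoculations, 4515 genes were higher. They were chosen from the same leaf libraries that are scored here, so that these scores are not an independent check. The inoculated ozone leaves scored 0.48, 0.51, 1.47 and 1.13 in replicates 1, 2, 3 and 4, or 0.90 ± 0.48 (SD, n = 4). The non-inoculated ones scored 0.42 ± 0.39 (SD, n = 4, exact permutation p = 0.171, not adjusted). The difference between the counts of 6673 and 68 is therefore not shown to be a difference between inoculated and non-inoculated leaves.

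**Figure D2:**
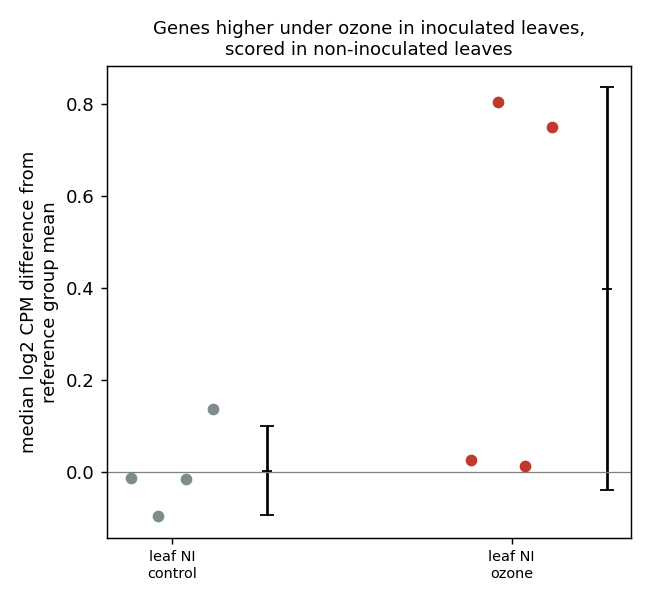
Score of the 4227 genes that ozone raised in inoculated leaves, measured in the 8 non-inoculated leaf libraries as the median log2 CPM difference from the mean of the controls; points are libraries, bars the mean ± SD of 4. Ozone replicates 2 and 4 lie at 0.81 and 0.75 and replicates 1 and 3 at 0.03 and 0.01, within the control range of -0.10 to 0.14.

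In leaves, edgeR called 1 gene changed by 43 h of stopped watering, and the same identifier was the 1 gene called for inoculation in control leaves. Potri.007G036400 had 43 to 77 counts per library in non-inoculated leaves without watering and 0 to 3 in their controls (n = 4 each; log2 fold change 5.21, edgeR adjusted p = 8.06e-05). In inoculated leaves it went the other way, with 0 to 3 counts without watering and 21 to 72 in controls (n = 4 each; log2 fold change -4.48, edgeR adjusted p = 0.00136). Inoculated control leaves exceeded non-inoculated ones by 4.33 (edgeR adjusted p = 0.00257), and the interaction was -9.68 (edgeR adjusted p = 5.87e-07). These fitted values involve libraries at 0 counts and depend on the prior count. The gene was chosen after its values were seen. The call in inoculated leaves without watering and that between control leaves were lost when only the compared groups were fitted, which called 0 genes in each. For stopped watering, 517 genes of non-inoculated and 500 of inoculated leaves had an unadjusted edgeR p under 0.05, fewer than the 1262 expected by chance. Recovery of changed genes was not simulated for these comparisons. The near absence of calls therefore does not exclude a wider response of leaves.

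**Figure D3:**
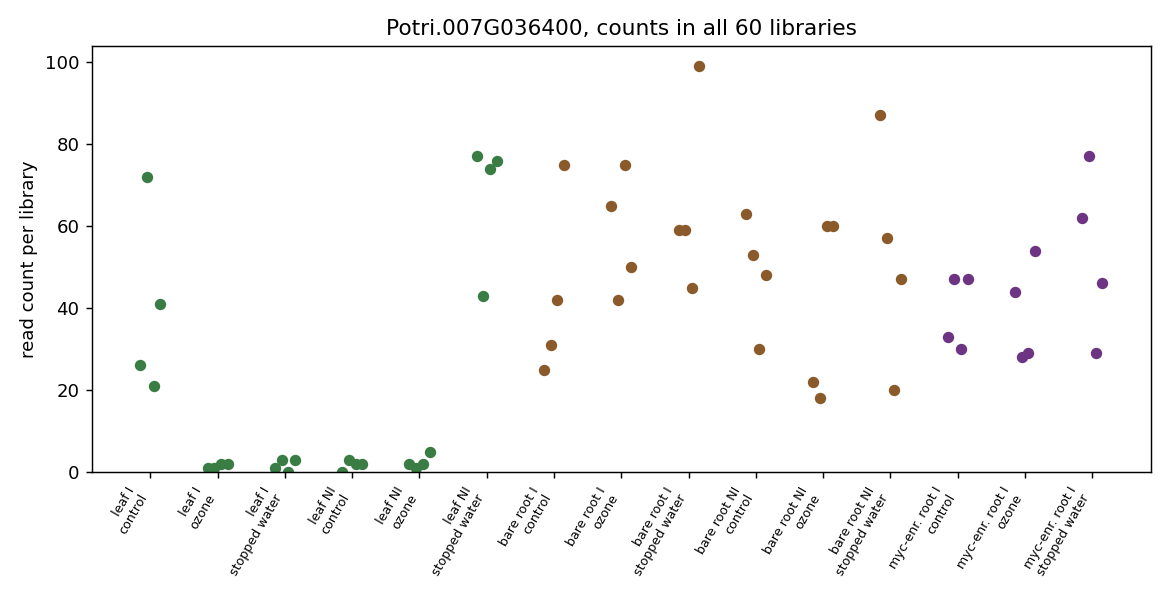
Read counts of Potri.007G036400 in all 60 libraries, 1 point per library, by organ, inoculation (I or NI) and treatment. Inoculated control leaves (21 to 72) and non-inoculated leaves without watering (43 to 77) lie apart from the other 4 leaf groups (0 to 5), while all root libraries lie between 18 and 99.

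In bare fine roots, stopped watering raised more genes than it lowered. In non-inoculated plants 172 genes were higher and 27 lower out of 27553. Potri.017G099500 rose from 0.532 ± 0.311 to 15.3 ± 7.36 CPM (SD, n = 4 each; log2 fold change 4.80, SE 0.57, edgeR adjusted p = 0.000446) and Potri.016G046350 from 2.19 ± 0.82 to 32.0 ± 23.4 CPM (SD, n = 4 each; log2 fold change 3.86, SE 0.65, edgeR adjusted p = 0.00521). Potri.009G040000 fell from 14.6 ± 0.97 to 5.73 ± 1.59 CPM (SD, n = 4 each; log2 fold change -1.35, SE 0.23, edgeR adjusted p = 0.00469) and Potri.001G301700 from 26.4 ± 6.79 to 10.9 ± 2.57 CPM (SD, n = 4 each; log2 fold change -1.28, SE 0.24, edgeR adjusted p = 0.0106). The count of 199 became 427 with DESeq2 and 45 in a fit of the compared groups alone. It was 76 and 104 without stopped-watering replicates 2 and 3, and 98, 58 and 70 without control replicates 1, 3 and 4.

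In bare roots of inoculated plants, stopped watering raised 38 genes and lowered 2. Potri.005G133900 rose from 1.25 ± 0.51 to 14.2 ± 8.52 CPM (SD, n = 4 each; log2 fold change 3.49, SE 0.59, edgeR adjusted p = 0.0231) and Potri.005G006800 from 1.81 ± 0.72 to 20.4 ± 10.6 CPM (SD, n = 4 each; log2 fold change 3.49, SE 0.54, edgeR adjusted p = 0.0157). Potri.009G040000, which had fallen in non-inoculated roots, fell here from 10.3 ± 2.62 to 4.34 ± 0.73 CPM (SD, n = 4 each; log2 fold change -1.24, SE 0.23, edgeR adjusted p = 0.0348). The count of 40 was 161 with DESeq2 and 0 in a fit of the compared groups alone. It was 11 and 0 without stopped-watering replicates 1 and 2, and 0, 24, 0 and 18 without control replicates 1, 2, 3 and 4.

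The rising genes of both root groups coincided: 28 were called higher in both, where independent lists would share 0.237, and 1 gene was called lower in both. Of the 172 genes raised in non-inoculated roots, 97.7% had a positive log2 fold change in inoculated roots, with a median of 0.88 against 1.37. The Pearson r across the 27553 genes was 0.52. The interaction of stopped watering with inoculation called 1 gene, Potri.008G210639 (log2 difference 1.97, SE 0.25, edgeR adjusted p = 0.00215), which had 31.1 ± 2.82 CPM without watering and 17.0 ± 2.52 CPM in controls of inoculated roots (SD, n = 4 each). In non-inoculated roots it went the other way, with 172 to 327 counts without watering and 429 to 746 in controls (n = 4 each). The difference between 199 and 40 calls is thus not shown to be an effect of inoculation. In that interaction 845 genes had an unadjusted p under 0.05, fewer than the 1378 expected by chance, and DESeq2 called 2.

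In mycorrhiza-enriched roots, stopped watering raised 22 genes and lowered 17 out of 26335. Potri.005G133900 rose from 1.84 ± 0.83 to 25.5 ± 11.9 CPM (SD, n = 4 each; log2 fold change 3.78, SE 0.39, edgeR adjusted p = 0.00775). Potri.005G006800 rose from 1.82 ± 0.73 to 35.0 ± 34.9 CPM (SD, n = 4 each; log2 fold change 4.27, SE 0.67, edgeR adjusted p = 0.0439), with 1 library far above the others. Potri.001G301700 fell from 19.2 ± 4.14 to 7.01 ± 1.28 CPM (SD, n = 4 each; log2 fold change -1.46, SE 0.21, edgeR adjusted p = 0.0251) and Potri.003G215001 from 10.8 ± 1.19 to 4.54 ± 0.46 CPM (SD, n = 4 each; log2 fold change -1.25, SE 0.15, edgeR adjusted p = 0.00809). Both rising identifiers were among the 4 genes called higher in all 3 kinds of root. The count of 39 was 409 with DESeq2 and 10 in a fit of the compared groups alone. It was 15 and 93 without stopped-watering replicates 2 and 3, and 7, 60, 6 and 11 without control replicates 1, 2, 3 and 4.

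As a group, the 172 genes raised in non-inoculated roots scored 0.86 ± 0.18 in unwatered bare roots of inoculated plants against -0.01 ± 0.19 in their controls, and the 163 of them measured in mycorrhiza-enriched roots scored 1.09 ± 0.66 against 0.00 ± 0.02 there (SD, n = 4 each). Every unwatered library lay above every control in both, with an exact permutation p of 0.0286 each, the smallest possible, and an adjusted p of 0.0971. The 27 falling genes scored -0.37 ± 0.06 and -0.40 ± 0.13 in the unwatered libraries of these organs (SD, n = 4 each; exact permutation p = 0.0286 each, adjusted p = 0.0971). In leaves, where 138 of the rising genes were measured, their score differed between unwatered and control libraries by 0.03 in non-inoculated and -0.07 in inoculated plants (exact permutation p = 0.771 and 0.486, n = 4 each, adjusted p = 0.85 and 0.635). In inoculated leaves under ozone, by contrast, these 138 genes scored 0.40 ± 0.14 against 0.005 ± 0.14 in controls (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0971), with every ozone library above every control. The falling root genes, of which 15 were measured in leaves, scored 0.32 ± 0.18 there against -0.02 ± 0.09 (SD, n = 4 each; exact permutation p = 0.0571, adjusted p = 0.177).

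**Figure D4:**
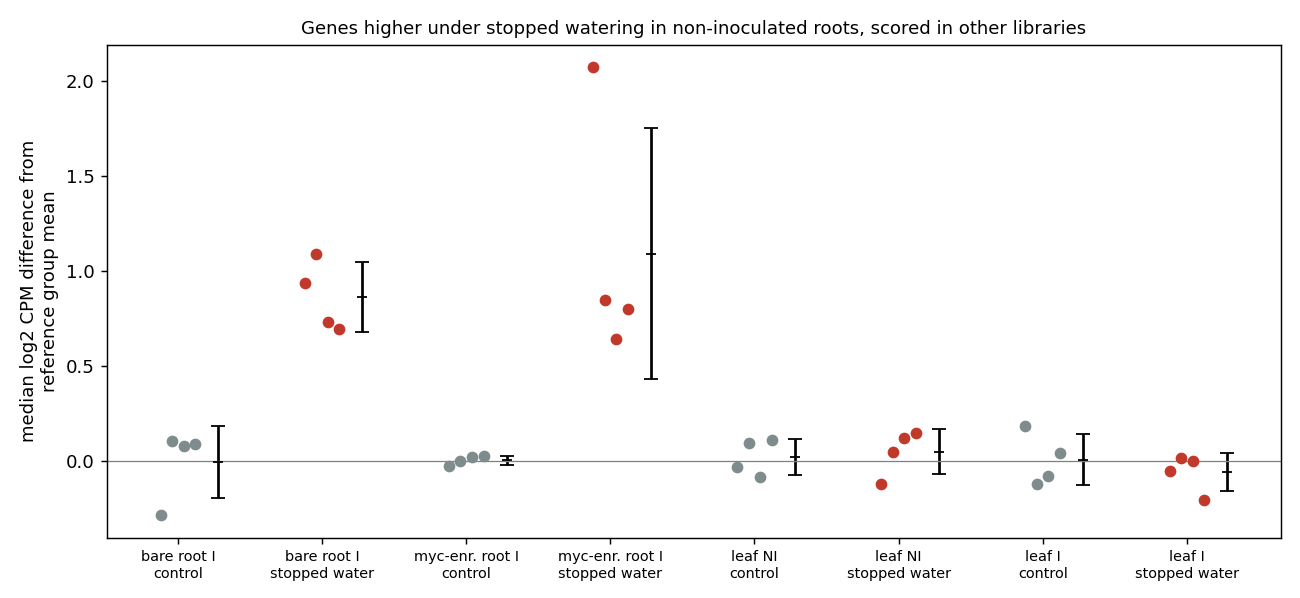
Score of the 172 genes that stopped watering raised in bare roots of non-inoculated plants, in libraries outside the 2 compared groups. The bare roots shown were in the same fit and shared its estimate of the spread. Of these genes, 163 were measured in mycorrhiza-enriched roots and 138 in leaves. Points are libraries, bars the mean ± SD of 4, and the axis is the median log2 CPM difference from the mean of the respective controls. Unwatered bare roots of inoculated plants lie at 0.69 to 1.09 and mycorrhiza-enriched roots at 0.64 to 2.08, while unwatered leaves lie at -0.21 to 0.14.

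Ozone called 0 genes below ground in edgeR's quasi-likelihood test. In bare roots, 4052 genes of non-inoculated and 1988 of inoculated plants had an unadjusted p under 0.05, against 1378 expected by chance, and DESeq2 called 111 and 31. In mycorrhiza-enriched roots 3222 genes had an unadjusted p under 0.05, with 1317 expected by chance, and DESeq2 called 100. The interaction of ozone with inoculation in bare roots called 0 genes (1885 at an unadjusted p under 0.05 with 1378 expected by chance, 1 by DESeq2). That of ozone with mycorrhiza enrichment also called 0 (1936 at an unadjusted p under 0.05 with 1354 expected by chance, 6 by DESeq2).

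Inoculation itself was examined in control plants. Bare roots of inoculated plants had 9 genes lower and 0 higher than roots of non-inoculated plants. In edgeR, 4463 genes had an unadjusted p under 0.05, where 1378 are expected by chance. Potri.012G042200 was at 4.70 ± 1.12 against 12.6 ± 2.69 CPM (SD, n = 4 each; log2 fold change -1.42, SE 0.24, edgeR adjusted p = 0.0426) and Potri.010G177000 at 5.82 ± 0.54 against 13.9 ± 4.18 CPM (SD, n = 4 each; log2 fold change -1.25, SE 0.21, edgeR adjusted p = 0.0426). No gene passed with RLE factors or in a fit of the compared groups alone, and DESeq2 called 488 (319 higher, 169 lower). Without inoculated replicate 3 the count was 291. It was 0, 1 and 0 without inoculated replicates 1, 2 and 4, and 0, 1, 2 and 1 without non-inoculated replicates 1, 2, 3 and 4. A contrast added after seeing the data took bare roots of control and stopped-watering plants together. It called 3498 genes for inoculation, 2008 higher and 1490 lower. Of 40 draws that exchanged inoculated and non-inoculated libraries, the real one alone reached 3498, but another reached 3252.

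Mycorrhiza-enriched roots differed widely from roots that had not met the fungus. In controls 3368 genes were higher and 3518 lower out of 26590, of which 942 and 442 differed by at least 1 on the log2 scale. Potri.006G055600 stood at 16.3 ± 9.13 against 1.01 ± 0.75 CPM (SD, n = 4 each; log2 fold change 3.97, SE 0.98, edgeR adjusted p = 0.0154) and Potri.001G451900 at 18.0 ± 16.3 against 1.97 ± 1.24 CPM (SD, n = 4 each; log2 fold change 3.18, SE 0.71, edgeR adjusted p = 0.0105). Potri.006G089901 was lower, at 2.37 ± 1.17 against 8.76 ± 2.10 CPM (SD, n = 4 each; log2 fold change -1.87, SE 0.31, edgeR adjusted p = 0.00309), as was Potri.006G037600, at 4.89 ± 1.38 against 16.7 ± 3.84 CPM (SD, n = 4 each; log2 fold change -1.77, SE 0.33, edgeR adjusted p = 0.00487). The count of 6886 was 4482 and 3535 without non-inoculated replicates 1 and 3 and 4209 without mycorrhiza replicate 1.

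Against bare roots of the same plants, mycorrhiza-enriched control roots had 778 genes higher and 1553 lower out of 27085. Among the called genes the median size was 0.47 on the log2 scale, against 0.59 in the comparison with non-inoculated roots. These medians come from different fits and different genes, so that they do not compare the size of the 2 effects. Of the called genes, 95 higher and 108 lower reached 1. Potri.010G000200 was at 114 ± 44.2 against 38.0 ± 9.11 CPM (SD, n = 4 each; log2 fold change 1.58, SE 0.33, edgeR adjusted p = 0.00946), while Potri.004G011101 was at 9.33 ± 1.06 against 23.0 ± 3.65 CPM (SD, n = 4 each; log2 fold change -1.30, SE 0.26, edgeR adjusted p = 0.00748). RLE factors gave 942 higher and 1357 lower, and DESeq2 gave 1499 and 1748. The total of 2331 was 361 in a fit of the compared groups alone, 851, 1070 and 1188 without bare root replicates 1, 3 and 4, and 705 and 1447 without mycorrhiza replicates 1 and 4. Without bare root replicate 2 it was 4290, and the direction turned, with 2161 higher and 2129 lower.

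Both groups of genes differed in the same direction under stress. The 778 genes higher in mycorrhiza-enriched control roots scored 0.26 ± 0.08 in mycorrhiza-enriched roots under ozone and 0.30 ± 0.14 without watering, relative to bare roots of the same treatment at 0.00 ± 0.05 and 0.00 ± 0.04 (SD, n = 4 each). The 1553 lower genes scored -0.23 ± 0.11 and -0.37 ± 0.11 (SD, n = 4 each). All 4 differences had an exact permutation p of 0.0286, the smallest possible for 4 against 4, and an adjusted p of 0.0971. As bare and mycorrhiza-enriched roots of the same number come from 1 pool, exchanges within pools allow 16 arrangements, and the p was then 0.125 for each, again the smallest possible. Between bare roots of inoculated and non-inoculated plants, the scores of the higher genes differed by -0.04 under ozone and 0.01 without watering (exact permutation test, n = 4 each, adjusted p = 0.635 and 0.854). The interaction of stopped watering with mycorrhiza enrichment called 1 gene, Potri.006G028700 (log2 difference -2.56, edgeR adjusted p = 0.0446), chosen after its values were seen and lost with the pool block and without a filter on low counts. The count was 0 when any of 14 of the 16 libraries was left out.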

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

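The tests of an exchange with a control library, of exchanged whole pools, of exchanged inoculation labels and of scaling in mycorrhiza-enriched roots were chosen after their results were seen, as were the scores of gene groups. The draws for the 2 interactions with mycorrhiza enrichment were chosen after the result of other draws was seen. In groups of 4 libraries, values far from the others were sought by Dixon's ratio, which chance exceeds in about 1 of 20 groups. Of 145 such groups, some of which repeat the same libraries, 10 exceeded it, where 7 are expected by chance. Non-inoculated control leaf replicate 3 had 19105357 counts against 22722620 to 23463259 in the others (ratio 0.83). Among genes that met the naming rule, Potri.012G115400 in non-inoculated leaf ozone replicate 3 (9.28 CPM on unscaled totals against 7.48 to 7.69, ratio 0.884), Potri.009G040000 in non-inoculated root stopped-watering replicate 4 (8.66 against 4.90 to 5.47, ratio 0.847) and Potri.004G011801, not described above, in mycorrhiza control replicate 3 (4.84 against 4.07 to 4.18, ratio 0.864) stood apart. Potri.001G374600 had counts in inoculated control leaf replicate 1 but 0 in the other controls (ratio 1.0), and is not otherwise reported. In mycorrhiza-enriched roots without watering, replicate 1 stood apart for Potri.005G006800 (92.3 against 10.9 to 22.1, ratio 0.862) and for the score of the 172 root genes (2.08 against 0.64 to 0.85, ratio 0.859). For the same score inoculated root control replicate 1 lay at -0.29 against 0.07 to 0.10 (ratio 0.932). For the falling ozone genes of leaves, non-inoculated root control replicate 2 scored -0.10 against 0.02 to 0.04 (ratio 0.904).

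Effects that differed between groups by an interaction test were those of Potri.007G036400 in leaves (stopped watering by inoculation, -9.68), Potri.008G210639 in bare roots (stopped watering by inoculation, 1.97) and Potri.006G028700 (mycorrhiza enrichment by stopped watering, -2.56). Potri.008G210639 had 229 to 353 counts in inoculated control roots and 172 to 327 in non-inoculated roots without watering, against at least 411 in the other 4 bare root groups. Potri.006G028700 had 7 to 11 and 5 to 11 counts in those 2 groups. Non-inoculated control roots overlapped them, with 10 to 28 counts, and the remaining bare root groups had at least 17. Potri.007G036400 was high in leaves of inoculated controls and of non-inoculated plants without watering, the same 2 combinations of inoculation and treatment. The interaction that called it and Potri.008G210639 sets these 2 combinations against the other 2 without ozone. That both genes share them therefore follows in part from how they were chosen. Mycorrhiza-enriched control roots, from the same pools as the inoculated control roots, had 568 to 862 counts of Potri.008G210639 and 24 to 34 of Potri.006G028700. Whether these patterns have a common cause was not tested.

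Ozone scores were uneven among leaves of both inoculations, with an SD of 0.48 in inoculated and 0.39 in non-inoculated leaves on the 4515 genes, and in the latter 2 ozone libraries lay near the controls. In the non-inoculated leaves, which were tested, thinning all leaf libraries to the smallest total left the SD of the 4 scores on the 4227 rising genes at 0.433, from 0.438, and RLE factors left it at 0.445, which argues against depth and scaling as the cause. An exchange with a control library of the same inoculation would leave a control with a high score, but the highest control scored 0.138. The unwatered leaves of non-inoculated plants scored -0.12 to 0.10 on these genes, read after the scores were seen, which argues against an exchange with them in the same way. A wrong label from outside the non-inoculated leaves, an uneven exposure of the pools and a real difference in sensitivity stay open, and no biological explanation was tested.

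Potri.007G036400 was high in 2 of the 6 leaf groups, which share neither inoculation nor treatment, so no biological explanation was tested. Root RNA in these leaf libraries would bring other root transcripts, but 105 genes abundant in roots and nearly absent from other leaves stood at a median of 0.0499% of their root level, whereas this gene stood at 109% of its root level. A batch shared by the 2 groups would be expected to move many genes, but 3 genes separated them from the other 4, under the bound set beforehand, which argues against a batch of that kind. An exchange of control and unwatered labels of whole pools in 1 inoculation would turn the root response there, but the lowest unwatered bare root of inoculated plants scored 0.593 above the highest control on the 172 genes of non-inoculated roots, which argues against it. Exchanges of 2 kinds stay open: of leaf libraries alone, since over the 4 leaf groups without ozone labelled inoculation and stopped watering gave 0 genes each, so that the bound of the batch, set for exchanged labels too, was set aside after its value was seen; and of inoculated and non-inoculated pools, since over the 4 bare root groups without ozone labelled inoculation gave 3498 genes and the crossed contrast 1, but another of 40 draws reached 3252.

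In mycorrhiza-enriched against bare roots of inoculated plants, more genes were lower than higher. Thinning the 24 libraries to the smallest total left 1969 calls, of which 36.5% were higher, which argues against depth as the cause. Scaling and test are a candidate explanation: the share of higher genes was 33.4% with TMM, 41.0% with RLE and 46.2% with DESeq2. Without bare root replicate 2 the calls were 2161 higher and 2129 lower. Reads of the fungus counted on poplar genes were not analysed here, and a biological difference in direction stays open.

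Each pairwise comparison was set against the 35 splits of its 8 libraries, which count calls and do not test any single gene. The real split alone gave its number of genes, 1 of 35 splits, for ozone in non-inoculated leaves (68, highest other 0) and inoculated leaves (6673, highest other 5216), for stopped watering in inoculated leaves (1, highest other 0) and in roots of non-inoculated (199, highest other 1) and inoculated plants (40, highest other 0), for inoculation in control roots (9, highest other 0), and for mycorrhiza-enriched roots against bare roots of inoculated (2331, highest other 1357) and non-inoculated plants (6886, highest other 0). For ozone in inoculated leaves another split came close, with 5216 genes against 6673. Chance can be excluded for the listed counts, apart from those of 6673 and 2331, only before correction for the 14 pairwise comparisons. After correction chance is not excluded, since 1 of 35 is the smallest share possible. It cannot be excluded for the counts under stopped watering in mycorrhiza-enriched roots (39, highest other 163) and non-inoculated leaves (1, highest other 998) and for inoculation in control leaves (1, highest other 2), where 2 of 35 splits gave as many. Counts of 1 decide nothing about the gene concerned, which is Potri.007G036400 in all 3 leaf comparisons. Where the real count was 0, for ozone in the 3 kinds of root, all 35 splits give as many by construction and decide nothing (highest other 1456 in non-inoculated, 642 in inoculated and 0 in mycorrhiza-enriched roots). Of the 8 splits that part every pair of bare and mycorrhiza-enriched libraries of 1 pool, the real one gave 2331 genes and the highest other 0. The other splits put both libraries of a pool on one side and ignore the pairing. As 1 of 8 is the smallest share possible with the pairing kept, chance is not excluded for the count of 2331.

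Interactions with inoculation were set against 40 draws that exchanged inoculated and non-inoculated libraries within a treatment, and those with mycorrhiza enrichment against 40 draws that exchanged treated and control libraries within a kind of root. For the ozone interactions the real count was 0, so that 40 of 40 draws reach it by construction and decide nothing (highest other 1425 in leaves, 746 in bare roots and 14 with mycorrhiza enrichment). For the 1 gene of each stopped-watering interaction, 2 draws gave as many in leaves and in bare roots (highest other 1 in both), so that chance is not excluded for these counts. With mycorrhiza enrichment 1 of 40 draws, the real one, gave as many (highest other 0). An earlier scheme, which exchanged the kinds of root within a treatment, gave 3 of 40 (highest other 5472), but it carries the large difference between the kinds of root into the interaction. As the 2 schemes disagree and the second was chosen after the first was seen, chance is not excluded for this call either.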

How the results depend on the processing

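The alternatives for overlaps and scores were chosen after seeing the data; the others were planned. Tests of gene lists and of fungal reads were not run because no list or fungal gene could be matched. The cause of the changes below was not tested, except that a minimum fold change removes genes by construction. Fits of the compared groups alone and of fewer libraries hold less information on the spread. Fits of the compared groups alone also no longer share its estimate with the other groups, and these 2 differences were not separated. With DESeq2 the counts were 1150 for ozone in non-inoculated leaves, 2 for inoculation in control leaves, 5 for the leaf ozone interaction, 111 and 31 for ozone in roots of non-inoculated and inoculated plants, 427 and 161 for stopped watering there, 488 for inoculation in roots, 1 and 2 for the root interactions with ozone and stopped watering, 100 and 409 for ozone and stopped watering in mycorrhiza-enriched roots, and 6 and 3 for the interactions of mycorrhiza enrichment with ozone and stopped watering. In fits of the compared groups alone they were 1 and 2821 for ozone in non-inoculated and inoculated leaves, 0 for stopped watering in inoculated leaves, 0 for inoculation in leaves and in roots, 45 and 0 for stopped watering in roots of non-inoculated and inoculated plants, 1 for ozone in inoculated roots, 3 and 10 for ozone and stopped watering in mycorrhiza-enriched roots and 361 for mycorrhiza-enriched against inoculated roots. With a log2 fold change of at least 1 they were 29 and 2321 for ozone in leaves, 119 for stopped watering in non-inoculated roots, 4 for inoculation in roots, 203 and 1384 for mycorrhiza-enriched against inoculated and non-inoculated roots, and 11 in place of 41 genes shared by both ozone responses of leaves. RLE factors gave 0 for inoculation in roots and moved no other count by more than 1.5 times. Without a low-count filter, inoculation in roots gave 4 and the interaction of mycorrhiza enrichment with stopped watering 0.

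With the replicate block, ozone in non-inoculated leaves gave 29 genes, stopped watering 61 in inoculated and 5 in mycorrhiza-enriched roots, inoculation in roots 2 and, with the pool as block, the interaction of mycorrhiza enrichment with stopped watering 0; the block moved no other count by more than 1.5 times. Across treatments these libraries share only a number, and in no pair of groups did all 4 libraries correlate best with their own number. Leaving out each library in turn gave 1 to 668 genes for ozone in non-inoculated and 3279 to 9459 in inoculated leaves, and 0 to 2 for the leaf ozone interaction. In roots it gave 0 to 1 for ozone in either group, 58 to 268 and 0 to 50 for stopped watering in non-inoculated and inoculated plants, 0 to 291 for inoculation and 1 to 2 for the stopped-watering interaction. With mycorrhiza-enriched roots it gave 0 to 1 for ozone, 6 to 93 for stopped watering, 705 to 4290 and 3535 to 7211 against inoculated and non-inoculated roots, and 0 to 1 for both interactions. No named gene changed direction under any setting. The call was lost in 61 of 248 leave-one-out fits of named genes, 13 of 29 fits of the compared groups alone, 7 of 26 with the replicate block, 2 of 30 with RLE factors and 1 of 30 without the filter. No score passed the correction under RLE factors or with groups limited to a log2 fold change of at least 1. A smallest p of 0.0286 can pass over 34 tests only where many of them reach it. With exchanges within pools no score could pass, since the smallest possible p was 0.125. Mycorrhiza-enriched roots had the lowest mean total of the 3 organs.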

Other observations

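Genes that rose together tended to have neighbouring identifiers. The number of pairs of tested genes that follow each other in identifier order and were both called higher was compared with 10000 permutations of the calls within 10 bins of expression, a test planned before its result was seen. For ozone in inoculated leaves 1228 pairs were found against a mean of 707, a ratio of 1.74 (permutation p = 1e-04, the smallest that the permutations can give). For stopped watering in non-inoculated roots there were 5 pairs against 1.07 (ratio 4.69, permutation p = 0.004), and for mycorrhiza-enriched against bare roots of inoculated plants 39 against 23.1 (ratio 1.69, permutation p = 0.001). One hypothesis is that neighbouring copies of a gene family respond together. Reads shared between near-identical neighbours could give the same excess, and without gene sequences these cannot be separated here.

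Of the 4227 genes raised by ozone in inoculated leaves, 4026 were measured in bare and 3961 in mycorrhiza-enriched roots. They scored 0.19 higher under ozone in bare roots of non-inoculated plants and -0.10 in mycorrhiza-enriched roots (difference of means, n = 4 each, exact permutation p = 0.0857 in both, adjusted p = 0.208). In bare roots of inoculated plants the difference was 0.06 (exact permutation p = 0.543, n = 4 each, adjusted p = 0.684). The genes that ozone lowered in inoculated leaves, of which 2316 were measured in mycorrhiza-enriched and 2355 in bare roots, differed by 0.09 in mycorrhiza-enriched roots, with every ozone library above every control (exact permutation p = 0.0286, n = 4 each, the smallest possible, adjusted p = 0.0971). In bare roots they differed by -0.10 in non-inoculated and -0.03 in inoculated plants (exact permutation p = 0.114 and 0.571, n = 4 each, adjusted p = 0.259 and 0.694). None of these differences passes the correction over the 34 tests.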
